A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

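The series holds 2 barcode microarrays of a genetic interaction mapping (GIM) screen in the budding yeast *Saccharomyces cerevisiae*. Per the labels' protocols, a pool of barcoded DAmP strains was crossed with mutant query strains, haploid double mutants were selected, and the pool grew for 18 generations with G418 and nourseothricin. The protocol speaks of 3 mutant strains without naming them, and only the 2 arrays of this series were analysed here. DAmP alleles lower the mRNA level of a gene by disturbing its 3′ untranslated region. Genomic DNA was extracted, and the barcodes were amplified with Cy3-tagged primers for the query pool and Cy5-tagged primers for a reference pool. Both pools were hybridised to the same 2-colour Agilent array. The series text calls the screens independent, so the arrays were treated as 2 replicates of a single group. The labels name no separate cultures, so part of the spread between the arrays may be technical. The number of arrays limits the precision of every value.

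The deposited values are a log ratio of both channels for each probe, read here as log2. The base, centring, direction, normalization and filter on dim spots are not given in the sources used here. The range of the values, from -4.79 to 3.91 on array 1 and from -6.36 to 9.40 on array 2, exceeds what a log10 ratio of 2 array brightnesses would reach, which is the reason for reading them as log2; a natural log is not excluded. If the base differed, every log ratio given here would be multiplied by 1 constant, and the folds and the counts beyond a limit in log2 units would change as well. The column medians were -0.06 on array 1 and -0.27 on array 2, and centring on these medians moved all genes of array 2 by 0.27. The direction was taken as query pool over reference pool. It is likely rather than stated, and its basis is the low ratio of genes next to the *PIH1* locus. Channel intensities were not analysed here.

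Of 15744 probes listed, 10998 (69.9%) had a value on array 1, 10382 (65.9%) on array 2 and 10226 on both. The platform annotation named 1 gene symbol for 13084 probes and none for 2660; no probe had several. These were 5100 symbols, updated through a gene table of the R64 assembly, which served only for names and for which genes neighbour each other. Of these, 5034 were current symbols there and 64 were synonyms of 1 gene; the other 2 matched several genes and were left out. The 5094 genes probed mostly had 2 probes (3706 genes) or 4 probes (1259 genes), and 86 had 1. Probes of a gene were averaged per array. Where exactly 2 probes of a gene had a value, they correlated across genes with r = 0.879 on array 1 (2445 genes) and r = 0.896 on array 2 (2251 genes), and differed by over 1 log2 unit for 2.13% and 6.57% of these genes. Probes name genes only, so the values do not tell a DAmP allele from another allele of the same gene, and each is called the value of a gene.

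A value on both arrays was present for 4196 genes. The 148 of them within 100 kb of *PIH1* or *RSA1* were kept out of the tests, which left 4048 genes. Linkage to the query locus lowers the ratio of its neighbours, and the labels name both genes as the query. Another 202 genes had a value on 1 array only and 696 on neither. Centred ratios were fitted with limma 3.58.1 (R 4.3.3; lmFit with an intercept, eBayes), tested against 0 and adjusted by Benjamini-Hochberg at 0.05. This test leaves out the spread of the reference pool. With 2 arrays, an exact two-sided sign-flip test cannot go below p = 0.5, so calls rest on limma's variance shared across genes. Tested on simulated data with the fitted spread of the 4048 genes (20 runs), the fit called 0.14% of unchanged genes. It called 0.7% of genes changed by 1 log2 unit, 32.5% at 2, 80% at 3 and 90% at 4. The simulated spread did not depend on the size of the change, whereas in the data it grew with the ratio. The median SD was 1.56 for genes with a mean at or above 2 and 0.18 for genes within 0.5 of 0. These shares can thus not be read as the share of real changes called here.

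Gene lists were tested with camera at a preset inter-gene correlation of 0.01, over the 22 lists with at least 4 measured genes, with Benjamini-Hochberg adjustment. In simulated data a shift of 0.5 in the ribosomal protein list was called in 20 of 20 runs, and 0 of 420 tests of other lists were called. Genes were simulated as independent, so these runs cannot show how often a list of correlated genes is called without a shift. Linkage was measured as the median ratio of genes within 50 kb of a locus, given as a percentile among all windows of as many neighbouring genes. Overlap between arrays was set against 10000 shuffles of the genes of array 2. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for these steps and for the figures.

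The design, the gene lists, the alternative settings and the rule for naming genes were fixed before the data were examined. The rule names *PIH1*, *RSA1*, *TAH1* and *HIT1*; the 15 most negative and 15 most positive genes that pass, or, with fewer than 5 at an end, the 10 most extreme with the same sign on both arrays; every measured gene of the R2TP and HSP90, box C/D and box H/ACA lists; 4 leading genes of each list that passes; and the 4 lowest genes of a linkage window that stands out. Alternatives changed the centring, the scaling between arrays (a common median absolute deviation, or quantile normalization), the averaging of probes, the filter on genes that differ between arrays by over 2 log2 units, robust eBayes, the linkage windows, a local trend over 41 neighbouring genes, the correlation in camera, and random lists in its place. Counts of genes beyond 1 log2 unit on both arrays, and single probes tested after scaling, were added after seeing the data.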

Results

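The screen measured which yeast mutations changed in abundance when combined with the deletion of a query gene. In each of 2 independent screens, barcodes of haploid double mutants were compared by hybridisation with those of a reference pool, and the log2 ratio of query pool over reference pool was obtained per gene. Titles name *PIH1* as the query gene, while the descriptions and source names give *RSA1*. Pih1 is a subunit of R2TP, an HSP90 co-chaperone with Rvb1, Rvb2 and Tah1 that helps assemble box C/D small nucleolar ribonucleoproteins (snoRNPs), and Rsa1 is an assembly factor of the same particles. Values were listed for 4370 genes on array 1 and 4224 genes on array 2, with 4196 on both. Negative ratios likely mean fewer double mutants in the query pool; the basis is the genes around *PIH1*, and the sources state no direction.

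Genes next to *PIH1* had low ratios in both screens. *PUT2* stood at -3.44 ± 1.07 (SD, n = 2), *BRL1* at -3.06 ± 1.19, *YHI9* at -2.33 ± 1.31 and *DAP2* at -2.22 ± 0.67, the 4 lowest genes of that region. Few recombinants form between a query deletion and its neighbours, so double mutants of neighbouring genes are rare in this kind of screen, and their ratio served as a check of the labels. Of 34 genes within 50 kb of *PIH1*, itself included, 30 had a negative mean, with a median of -1.01 (quartiles -1.29 and -0.61). That median lay at percentile 0.218 of 3668 windows of as many neighbouring genes. The lowest median among 3539 windows over 200 kb away from *PIH1* was -0.25. By array the median was -1.16 and -0.83. The ratio returned to 0 with distance: the 10 genes closest to *PIH1* had a median of -1.96 and all 10 were negative on both arrays, the next 10 had -1.09, neighbours 11 to 20 on each side -0.63, neighbours 21 to 40 -0.20 and neighbours 41 to 60 -0.01.

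Around *RSA1* no such drop was seen. The 42 genes within 50 kb had a median of 0.04, at percentile 72.5 of its windows, and 18 of them were negative. The query named in the titles, *PIH1*, thus had the linked low region and the query named in the descriptions did not. The *PIH1* gene itself stood at 1.01 ± 0.01, from 2 probes on array 1 and 1 on array 2. Linkage would make this value low as well, so it goes against the pattern of its neighbours. The cause was not tested. *RSA1* and *HIT1*, which encodes a partner of Rsa1, had probes but no listed value. *TAH1* stood at -0.01 ± 0.04.

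**Figure D1:**
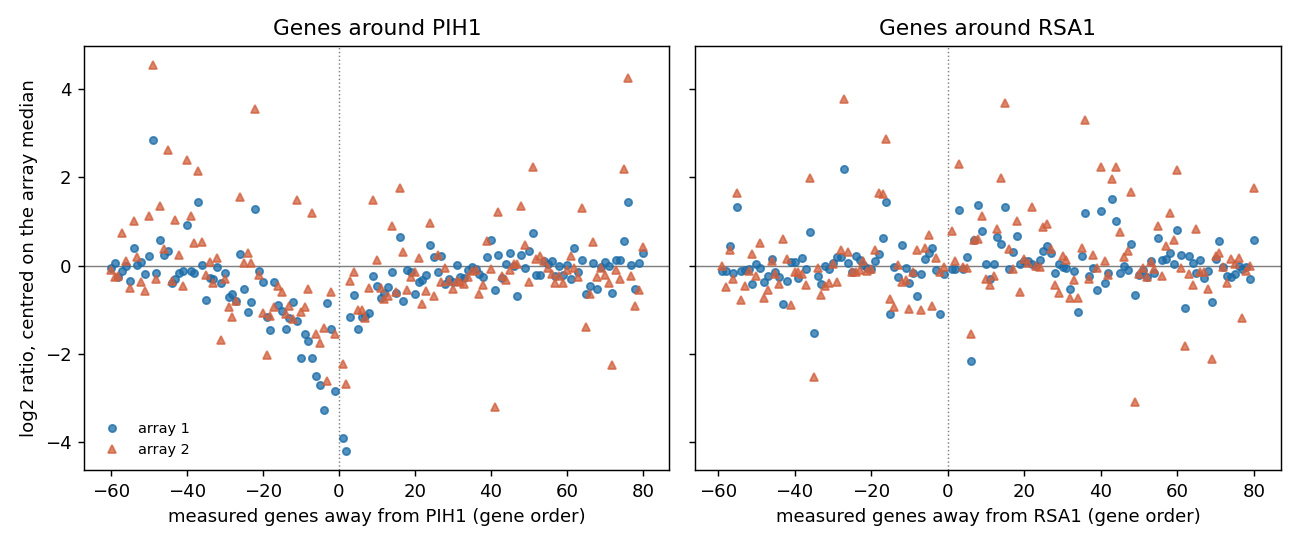
Log2 ratio of each gene (query pool over reference pool, centred on the array median; circles array 1, triangles array 2) against its distance from PIH1 (left) or RSA1 (right), counted in measured genes along the chromosome. The 10 genes closest to PIH1 have a median of -1.96, and those closest to RSA1 a median of 0.03.

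The screens agreed on which genes had low or high ratios. Per the protocol the query pool carried Cy3 and the reference pool Cy5, and no array of another query was analysed. Agreement therefore cannot tell an effect of the query from a bias that both arrays share, such as that of a dye or a reference pool. Among the 4048 genes outside both regions, 82 were at or below -1 on both arrays and 259 at or above 1 on both, while 3 were beyond 1 in opposite directions. Shuffling the genes of array 2 gave a mean of 6.27 (highest 18), 48.1 (highest 76) and 35.1 (lowest 16) in its place, each with a one-sided permutation p = 1e-04, the smallest that 10000 shuffles can give. Across genes, which are not independent replicates, the arrays correlated with Pearson r = 0.762 and Spearman rho = 0.595. Their scale differed. On array 1, 23 genes were at or below -2 and 70 at or above 2, against 58 and 333 on array 2, and the slope of array 2 on array 1 was 2.26.

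**Figure D2:**
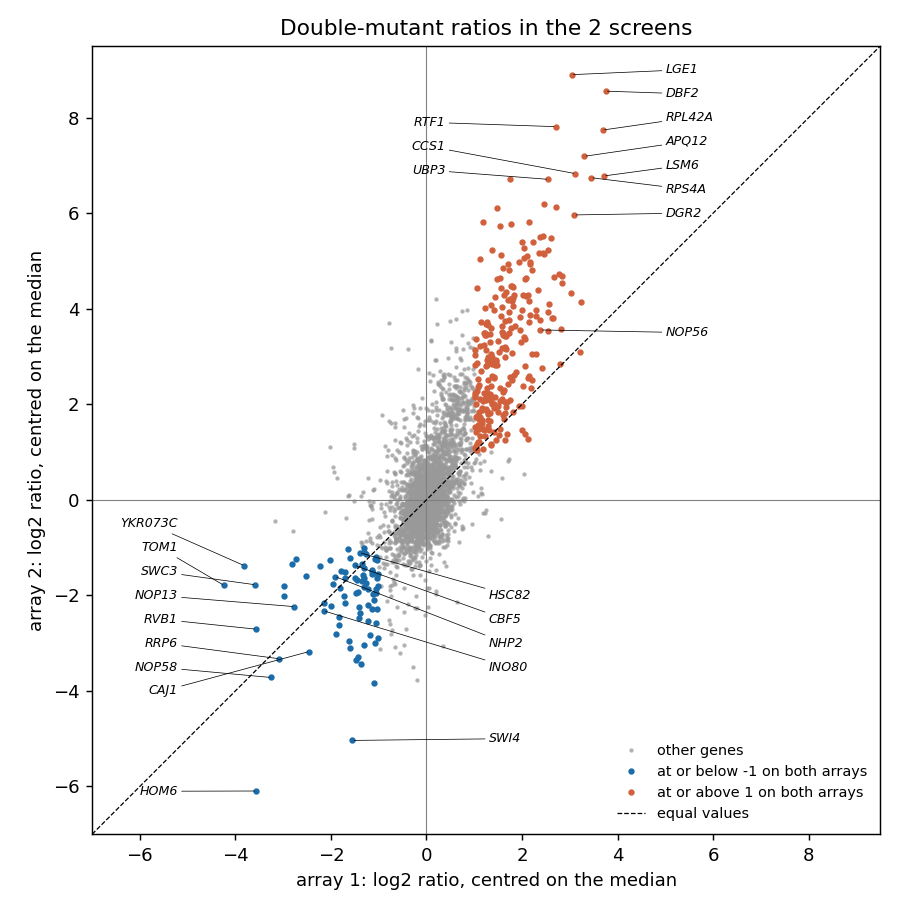
Log2 ratio of each of 4048 genes on array 1 (horizontal) and array 2 (vertical), both centred on the array median, with the dashed line at equal values. The 82 blue genes lie at or below -1 and the 259 red genes at or above 1 on both arrays, and the red genes lie mostly above the line.

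Outside the regions around *PIH1* and *RSA1*, the lowest ratio belonged to *HOM6*, homoserine dehydrogenase of threonine and methionine synthesis, at -4.83 ± 1.79, or 28.4-fold lower (mean ± SD over 2 arrays, here and below). Next came *NOP58*, a core protein of box C/D snoRNPs, at -3.49 ± 0.33 (11.2-fold lower), and the G1/S transcription factor gene *SWI4* at -3.29 ± 2.46. *RRP6*, a nuclear exosome exonuclease, stood at -3.20 ± 0.18 (9.21-fold lower), and *RVB1*, an ATPase shared by R2TP, INO80 and SWR1, at -3.14 ± 0.61 (8.79-fold lower). The ubiquitin ligase gene *TOM1* stood at -3.01 ± 1.73, the J-domain protein gene *CAJ1* at -2.82 ± 0.51, the SWR1 subunit gene *SWC3* at -2.68 ± 1.28, *YKR073C* at -2.60 ± 1.73 and *NOP13*, encoding a nucleolar protein, at -2.50 ± 0.37.

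At the other end, again outside these regions, *DBF2*, a kinase gene of mitotic exit, had a ratio of 6.15 ± 3.40 and *LGE1*, which acts with the ligase Bre1 in histone H2B ubiquitination, 5.97 ± 4.14. The ribosomal protein genes *RPL42A* and *RPS4A* stood at 5.71 ± 2.86 and 5.09 ± 2.33. *RTF1*, a Paf1 complex subunit gene, stood at 5.26 ± 3.61, *LSM6*, of the Sm-like RNA-binding rings, at 5.25 ± 2.17, and *APQ12*, a nuclear envelope gene, at 5.25 ± 2.75. The copper chaperone gene *CCS1* was at 4.97 ± 2.63, the deubiquitinase gene *UBP3* at 4.63 ± 2.94 and *DGR2* at 4.53 ± 2.03. All 10 had the larger value on array 2.

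None of these genes passed the test. By limma, 0 of 4048 genes were called (smallest adjusted p = 0.227), and 678 had an unadjusted p under 0.05, of which 201 were negative and 477 positive. The spread grew with the ratio: the median SD between arrays was 1.56 for the 169 genes with a mean at or above 2, 0.99 for the 30 genes at or below -2, and 0.18 for genes within 0.5 of 0. After the arrays were scaled to a common median absolute deviation, limma called 489 genes (100 negative, 389 positive), and after quantile normalization 408 (64 negative, 344 positive). Both scalings shared 401 calls, 61 negative and 340 positive.

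The R2TP and HSP90 list had low values for the ATPase gene *RVB1* (-3.14 ± 0.61), the HSP90 gene *HSC82* (-1.25 ± 0.21), and the co-chaperone genes *STI1* (-1.13 ± 0.31) and *SBA1* (-0.83 ± 0.30). *HCH1*, an activator of HSP90, stood at -0.48 ± 0.01. *AHA1* (-0.18 ± 0.01), *SGT1* (-0.09 ± 0.19), *CNS1* (-0.05 ± 0.53), *TAH1* and *PPT1* (0.02 ± 0.53) lay near 0, *SSE2* at 0.45 ± 0.39 and *CPR6*, a cyclophilin gene, at 0.90 ± 0.22. *HSP82*, the other HSP90 gene of the list, had a mean of -0.25 (-0.07 on array 1 and -0.43 on array 2). Like *PIH1*, it lay in a region kept out of the tests. The list as a whole missed the threshold (12 of 19 genes tested, median -0.13, camera adjusted p = 0.0507). Its median was -0.39 on array 1 and -0.20 on array 2. In this list 3 genes passed when adjusted over the list alone and 0 over all genes.

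Box C/D snoRNP genes went both ways. *NOP58* was at -3.49 ± 0.33, while *NOP56*, which encodes the paralogous core protein, was at 2.97 ± 0.83. *SNU13*, a core protein gene, stood at -0.82 ± 0.65 and *RRP9*, of the U3 snoRNP, at -0.57 ± 0.36. In the box H/ACA list the core protein gene *NHP2* stood at -1.76 ± 0.22 and the pseudouridine synthase gene *CBF5* at -1.44 ± 0.10, while the assembly factor genes *SHQ1* (-0.11 ± 0.03) and *NAF1* (0.12 ± 0.36) lay near 0. Neither list passed (camera adjusted p = 0.152 for box C/D and 0.0507 for box H/ACA, 4 genes each). In each, 2 genes passed when adjusted over the list alone.

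The cytoplasmic ribosomal protein list rose as far as it was tested, which covers 66 of its 138 genes (129 had probes). These 66 genes had a median of 1.72, and 43 were at or above 1 on both arrays and 0 at or below -1. Camera gave an adjusted p = 6.32e-17, and adjusted p = 0.609 with an estimated correlation. That estimate has 1 residual degree of freedom. Its smallest unadjusted camera p over all lists was 0.201, so it cannot decide for or against a shift, here or for the lists below. *RPL42A* and *RPS4A* led the ribosomal list, followed by *RPL8B* at 3.99 ± 2.59 and *RPL8A* at 3.69 ± 1.20. Adjusted over the list alone, 46 of its genes passed, against 0 over all genes. The mitochondrial ribosomal protein list also rose (51 genes, median 1.31, camera adjusted p = 2.75e-09; adjusted p = 0.609 with an estimated correlation). Their median was 0.56 on array 1 and 2.0 on array 2, 5 genes were at or above 1 on both, and 1, *MRPL13* (-1.59 ± 0.70, named after its values were seen), was at or below -1 on both. *MRP7* (3.82 ± 2.24), *MRPS16* (2.22 ± 1.45), *MRPL7* (1.83 ± 0.02) and *MRPL10* (1.74 ± 0.61) led, and 0 genes passed when adjusted over the list alone.

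All 5 measured genes of the CCT chaperonin and prefoldin, which fold actin and tubulin, were positive on both arrays (median 2.89; 1.67 and 3.82 by array). They were led by *TCP1* (3.01 ± 1.89), *YKE2* (3.01 ± 1.20), *CCT2* (2.89 ± 1.31) and *GIM4* (1.97 ± 0.80), and the list rose (camera adjusted p = 0.00123; adjusted p = 0.609 with an estimated correlation). Only 5 of its 16 genes were measured. The proteasome list rose, with a median of 1.13 over 31 genes (0.30 on array 1 and 1.72 on array 2; camera adjusted p = 3.79e-04; adjusted p = 0.609 with an estimated correlation). Of its genes, 19 were positive and 2 negative on both arrays, and 8 were at or above 1 on both. The 20S core genes *PRE10* (2.44 ± 1.82), *SCL1* (2.35 ± 2.27), *PUP2* (2.19 ± 1.04) and *PUP1* (2.11 ± 1.17) led. Adjusted over the list alone, 4 chaperonin and prefoldin genes and 0 proteasome genes passed.

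The nuclear pore and transport list rose, with a median of 0.55 over 28 genes (0.31 on array 1 and 0.94 on array 2; camera adjusted p = 2.75e-04; adjusted p = 0.609 with an estimated correlation). On both arrays 22 of its genes were positive, 2 were negative and 6 were at or above 1. *NSP1* (3.60 ± 2.13) and *NUP49* (2.35 ± 1.60) of the central channel, *POM34* (2.31 ± 1.11) of the pore membrane ring and the mRNA export gene *MTR2* (2.17 ± 1.03) led, and 0 passed when adjusted over the list alone.

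The list of the chromatin complexes INO80, SWR1 and NuA4 fell. Of 22 measured, 10 were at or below -1 on both arrays and 3 at or above 1, with a median of -0.53 and a mean of -0.30 (camera adjusted p = 0.00897; adjusted p = 0.609 with an estimated correlation, and 0.0647 after quantile normalization). *RVB1*, which also belongs to the R2TP list, and *SWC3* were lowest, followed by the ATPase gene *INO80* at -2.24 ± 0.12 and *ARP6*, of SWR1, at -2.14 ± 0.01. Adjusted over the list alone, 13 of its genes passed in either direction.

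**Figure D3:**
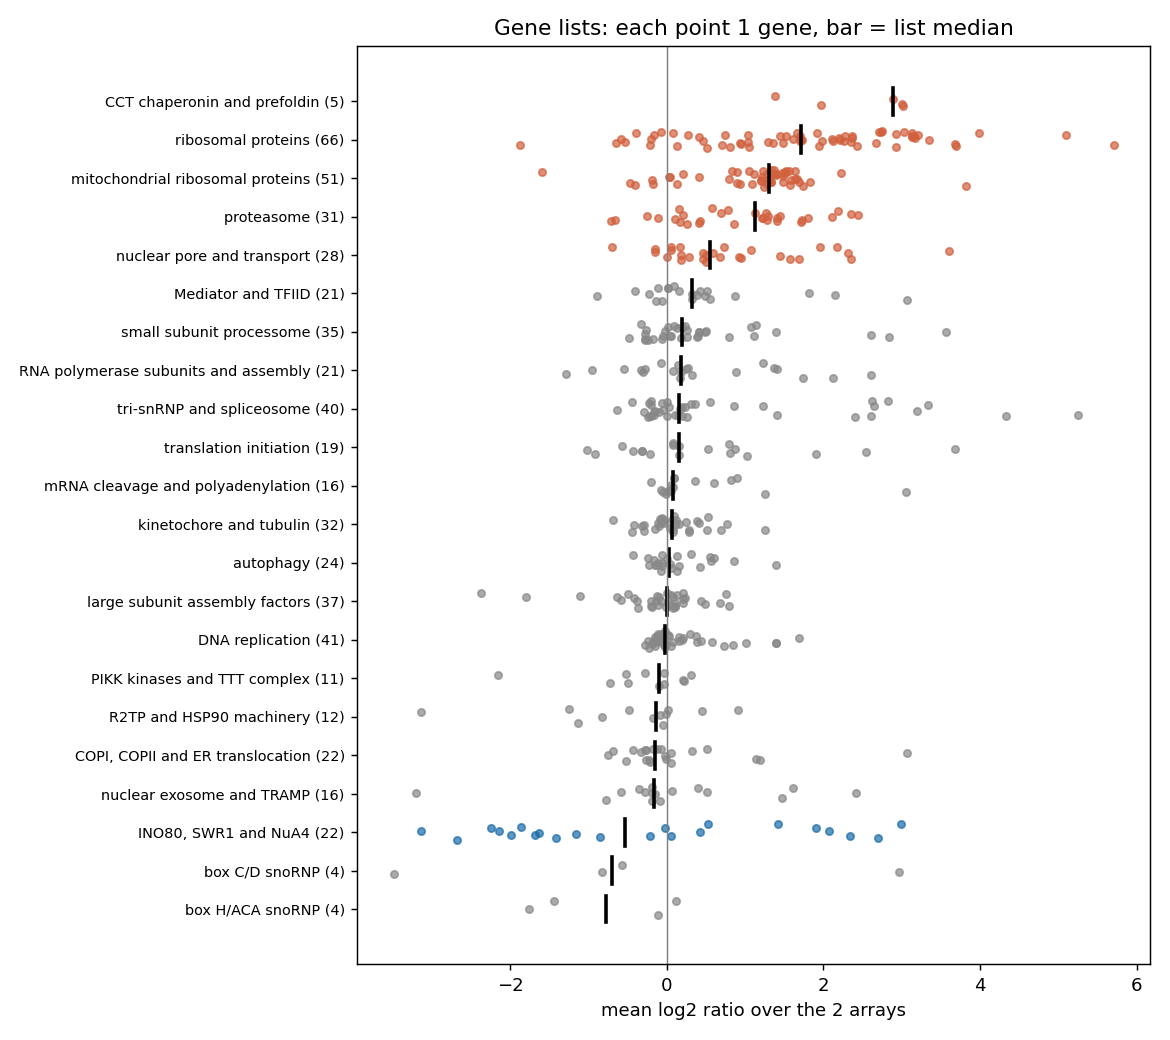
Mean log2 ratio over both arrays (horizontal) of every measured gene in 22 gene lists, with the number of genes in brackets and a bar at the list median. Lists with a camera adjusted p under 0.05 are red (higher) or blue (lower), and the medians run from -0.78 for box H/ACA snoRNP to 2.89 for CCT chaperonin and prefoldin.

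The other 13 lists did not pass by camera, with medians from -0.16 to 0.32. Spliceosome and tri-snRNP genes came nearest (40 genes, median 0.16, adjusted p = 0.0507), 10 of them at or above 1 on both arrays. Small subunit processome genes had a median of 0.19 (adjusted p = 0.0893), Mediator and TFIID genes 0.32 (0.144), mRNA cleavage and polyadenylation genes 0.09 (0.144) and genes of the PIKK kinases and their TTT co-chaperone -0.09 (0.144). RNA polymerase subunits and assembly factors had a median of 0.18 (0.304), translation initiation factors 0.15 (0.367), kinetochore and tubulin genes 0.07 (0.612) and autophagy genes 0.03 (0.463). The RNA polymerase median was -0.03 on array 1 and 0.40 on array 2, and the autophagy median 0.17 and -0.08. In 4 lists the median and the mean differed in sign. These were large subunit assembly factors (median 0.01, mean -0.12, tested lower, adjusted p = 0.276), the nuclear exosome and TRAMP (-0.16, 0.03, lower, 0.403), COPI, COPII and ER translocation (-0.15, 0.09, lower, 0.463) and DNA replication (-0.02, 0.19, higher, 0.449). The vacuolar ATPase list had 2 genes measured, too few for the test.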

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

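The counts of genes beyond 1 log2 unit on both arrays, and the fits of single probes after scaling, were chosen after seeing the data. Scaling between the arrays decided how many genes limma called: 0 as centred, 489 after scaling to a common median absolute deviation (459 of them by at least 1 log2 unit) and 408 after quantile normalization (407). Of the 58 genes named, 39 and 37 were called then. Before scaling, the median absolute deviation over probes (as an SD) was 0.35 on array 1 and 0.63 on array 2. Scaling takes this difference out of the spread between arrays. How far it alone accounts for the calls was not tested. The other 8 settings left 0 calls, with the smallest adjusted p from 0.0688 (genes differing by over 2 log2 units left out) to 0.254 (robust eBayes). Single probes after scaling gave 936 calls (median absolute deviation) and 913 (quantile) among 8526 probes. The correlation between arrays was 0.778 with the closest tag per gene and 0.734 over single probes. The count at or above 1 on both arrays, 259 as centred, was 171 with the genes that differ by over 2 left out, 326 after scaling to a common median absolute deviation and 374 after quantile normalization, and the count at or below -1 stayed between 76 and 98 in every setting run per gene. Each of the 6 lists that passed kept its direction in every alternative run, but none passed with an estimated correlation (adjusted p = 0.609 for each). There, 2 arrays leave 1 residual degree of freedom, and the smallest unadjusted camera p of any list was 0.201. That setting therefore cannot decide whether the shifts hold for correlated genes. The INO80, SWR1 and NuA4 list missed the threshold after quantile normalization (adjusted p = 0.0647, from 0.00897; its other alternatives ran from 7.33e-04 to 0.609); the cause was not tested. Against 10000 random lists, box C/D (adjusted p = 0.0233), box H/ACA (0.0269) and Mediator and TFIID (0.0484) also passed. The random lists compare the list median, whereas camera compares the average of the moderated statistics, so the tests do not ask the same question. In box C/D the median was -0.70 and the mean -0.48. Without 1 of the arrays no residual degrees of freedom remain, so counts of calls were not run that way. By single array, the *PIH1* region lay at percentile 0 to 0.436 and the *RSA1* region at 50.2 to 63.9. With windows of 25 kb and 100 kb, *PIH1* lay at 0.152 and 0, and *RSA1* at 45.0 and 49.4. Signal over background was not analysed here, so what dim spots limit is open.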

Other observations

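The gene sets of the first 2 paragraphs were chosen after their values were seen. So were the tests below of a deletion at *RSA1*, of a chance run of low genes, of 1 scale factor, of single probes, of scarce strains, and of 4 members alone in the INO80, SWR1 and NuA4 list. Of 7 measured genes of COMPASS, the histone H3 lysine methyltransferase complex, 6 were at or above 1 on both arrays: *SDC1* (3.94 ± 2.22, SD, n = 2), *SWD3* (3.80 ± 1.90), *BRE2* (3.70 ± 2.40), *SWD1* (3.50 ± 1.84), *SWD2* (3.05 ± 2.23) and *SPP1* (1.63 ± 0.86). The seventh, *SHG1*, stood at 0.28 ± 0.17. Of the 3 measured genes of the Paf1 complex, *RTF1* stood at 5.26 ± 3.61, *CDC73* at 4.24 ± 3.52 and *LEO1* at 1.12 ± 0.24. Of the 6 measured genes of the Lsm rings, which bind U6 RNA or decaying mRNA, 5 were at or above 1 on both arrays, from *LSM3* at 3.20 ± 0.54 to *LSM6* at 5.25 ± 2.17. The sixth, *LSM8*, stood at 1.23 ± 0.62. *CCS1* (4.97 ± 2.63) was joined by its client gene *SOD1* (3.66 ± 2.28) and the copper transporter gene *CTR1* (3.76 ± 1.97), and *UBP3* (4.63 ± 2.94) by the gene of its cofactor, *BRE5* (3.08 ± 2.78). The 2 measured genes of the vacuolar ATPase list, *VPH1* (3.04 ± 0.71) and *PKR1* (3.75 ± 1.38), were high too.

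Within 1 complex, genes stood on opposite sides. Of INO80, the genes *INO80* (-2.24 ± 0.12), *ARP4* (-1.98 ± 1.06) and *IES4* (-1.85 ± 0.14) were low on both arrays, whereas *IES2* (2.70 ± 1.63) and *ARP8* (1.42 ± 1.53) were positive on both. Of the 4 measured Nhp10 module genes, 1 was at or above 1 on both arrays, *IES5* (2.34 ± 1.57); *NHP10* (2.07 ± 1.71) and *IES3* (1.91 ± 1.96) were positive on both, and *IES1* (0.43 ± 1.10) had opposite signs on the arrays. SWR1 was mostly low, with a median of -1.63 over 9 genes and 6 of them at or below -1 on both arrays. These 6 include *RVB1* (-3.14 ± 0.61), also counted in INO80, and *ARP4*, also counted in INO80 and NuA4, so the complexes are not separate evidence. Yet *SWR1*, the gene of the SWR1 ATPase, stood at 0.52 ± 1.41. In NuA4, *EAF6* (-1.67 ± 0.35) and *EAF3* (-1.16 ± 0.11) were low, *EAF7* was at 2.99 ± 1.40, and *EPL1* (0.05 ± 0.11) and *ESA1* (-0.03 ± 0.24) lay near 0. The 5 measured genes of the CCR4-NOT complex were split as well. *NOT3* (3.36 ± 1.82) and *CDC36* (2.96 ± 1.87) were high, *CAF130* (-1.57 ± 0.16) and *CAF40* (-0.98 ± 0.39) low, and *CDC39* was at 0.23 ± 0.15. Ribosomal proteins of the small subunit (*RPS* genes) had a median of 2.73 (28 genes, 22 at or above 1 on both arrays). Those of the large subunit (*RPL* genes) had a median of 1.32 (36 genes, 19). The gap lay mostly on array 2, with medians of 3.544 and 1.29 there against 1.815 and 1.228 on array 1. The difference between the subunits was not tested, and the measured genes *RPP1B* and *RPP2A* of the ribosomal protein list were in neither set. Beside *HOM6*, the other measured genes of a set from threonine and methionine synthesis outside the *PIH1* region were *MET17* at -0.68 ± 0.49, *HOM2* at -0.02 ± 0.19, *MET2* at 0.36 ± 0.39, *THR4* at 0.37 ± 0.45 and *MET6* at 0.81 ± 0.88; *THR1* stood at -2.02 inside that region. Among 1449 probes with no gene named, 2.76% were at or below -1 on both arrays, against 1.78% of named probes, and 3.80% against 6.10% were at or above 1. Away from *PIH1*, the lowest median over 15 neighbouring genes was -0.49 (chromosome V, *RAD23* to *YEL014C*), and 31 of 1000 shuffles of gene order held a window as low; the highest was 1.15 (chromosome IV, *ATP17* to *SXM1*), with 88 of 1000 as high.

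The first pattern weighed is the run of low ratios around *PIH1*. A query deletion at *RSA1* alone would put the low region there, and the median around *RSA1* lay at percentile 72.5, which argues against it. A chance run would leave other windows as low, and 0 of 3539 windows over 200 kb away reached the median of the *PIH1* region. A deletion at *PIH1*, as the titles give it, is consistent with both results, as a hypothesis. A query marker at another gene close to *PIH1* would give the same run and was not tested. The ratio of *PIH1* itself, 1.01 ± 0.01, goes against the low value that linkage would give there, and it stays unexplained.

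The second is that positive ratios were larger on array 2. With 1 scale factor for all genes, those within 50 kb of *PIH1* should follow the slope of 2.26, but their median on array 2 was 0.785 of that on array 1 (95% bootstrap interval 0.472 to 0.928, 33 genes without *PIH1* itself). Noise of single probes is argued against by 185 genes whose first probe was at 2 or more on array 2, since their second probe had a median of 2.84. Scarce strains stay open: with blank probes as a stand-in for scarcity, 85 of 856 genes with a blank probe (9.93%) were at or above 2 on array 2, against 168 of 2100 with none (8.0%), a difference of 1.93 percentage points (95% bootstrap interval -0.35 to 4.29; Fisher's exact p = 0.0955). The genes near *PIH1* were mostly negative, so the quotient of 0.785 cannot tell linkage from the sign of the ratio. Low genes outside that region went both ways. The median of 9 SWR1 genes was -1.785 on array 1 and -1.233 on array 2, while 23 and 58 genes were at or below -2. A factor that acts on growth effects but not on linkage is thus neither shown nor excluded. The authors' normalization may also lie behind the difference. No biological explanation was tested because the labels give both screens the same group.

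The third is the shift of gene lists. A regional trend was argued against: after subtracting the median of 41 neighbouring genes, the 181 members of the 5 lists that rose kept 0.982 of their median, and the INO80, SWR1 and NuA4 median was -0.54. Whether that median rests on 4 genes alone stays open: without its 4 lowest it was 0.01, at percentile 24.9 of random lists that lost their 4 lowest as well. Its low members are more than those 4, as 6 of the other 18 were at or below -1 on both arrays. By chance 0.35 would be drawn (exact hypergeometric p = 6.55e-07). That test treats members of shared complexes as independent draws. Its outcome was also fixed by the 10 low members already counted in the list, so it adds no separate support. Strains that already grow slowly by themselves may reach other ratios than fast ones, and this stays open because growth of the single mutants was not analysed here.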
